A study of Mus musculus with 6 samples.

How the data were processed

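RNA of 6 mouse tumours was measured, 3 grown from GLMT1 cells in WT hosts and 3 in TNKO hosts. Per the labels' protocols, 100 microlitres of a suspension with 1e+07 cells per ml were inoculated, and biotinylated RNA was made from 100 ng of total RNA with a 3' in vitro transcription kit. The deposited table holds 1 value per probe set and array for 45101 Affymetrix probe sets, on a scale taken as log2 from the range of the values, and was normalized by the authors before deposit. R 2.7.2 is named in the submitters' processing notes. The summarization method, the normalization and the base of the logarithm are not given in the sources used here. Differences between arrays were strongly shrunk relative to usual array values, with a median residual SD of 1.78e-06, so a difference of 1 unit cannot be equated with a 2-fold change in RNA. Arrays give no read depth, and their number limits the precision.

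The 64 control probe sets were left out of the tests of genes, which left 45037. Gene names came from the platform's annotation table (2016), checked by gene identifier against a reference gene table, which changed 0 symbols and whose coordinates were not used. Of the tested probe sets 34945 had 1 gene symbol, 932 several and 9160 none. For a gene with several probe sets, the one with the highest mean over the 6 arrays stood for it, which gave 18194 genes. Between 21 and 43 values were identical, as written and with no tolerance, between the arrays of a pair, so no array was taken as a copy of another.

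Groups were compared as TNKO minus WT with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, no trend, not robust), on the values as deposited, two-sided, with Benjamini-Hochberg adjustment over the 45037 probe sets and a threshold of 0.05. Calls were also counted with an absolute difference of at least 1 unit. Residual SDs are those of the same fit before moderation. The 40 gene lists were fixed before the data were examined, and 753 of their 823 genes were matched to a probe set. Lists with at least 3 measured members, 39 in all, were tested with limma's camera with a preset correlation of 0.01, and again with an estimated correlation and with fry. List members were also adjusted over the list alone. The samples carry no batch label, and the replicate numbers were not taken as pairs.

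The genes named were set by a rule written before the data were examined. They are the tenascins, the 10 largest rises and 10 largest falls among genes with 1 symbol past the threshold and with groups that do not overlap, up to 3 members of each list with the smallest unadjusted p (given for lists that passed), and the Y-linked genes with Xist. A direction with fewer than 10 genes was filled with genes at an unadjusted p under 0.01, given as values. Named outside the rule are Tap1, Tap2, Hmgcs1, Myh1, the hair and epidermis genes and the control probe sets, chosen after their values were seen.

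The alternatives were quantile normalization, subtraction of array medians, eBayes with a trend or robust, array weights, only probe sets above the median level, an offset of 16 before log2, a replicate block, leaving out each array, a rank product with 100 permutations, the mean over the probe sets of a gene, an estimated correlation and fry. Fits without moderation, a filter on probe sets spanning at least 0.001, camera on ranks, the directions of lists and controls under each scaling, and the counts of the highest and lowest array per list were added after the data were examined.

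The procedures were tested on simulated data made from these probe sets and their spread. For 50 probe sets changed by each size, limma recovered 5 at 5 residual SDs, 40 at 10, 47 at 20 and 48 at 40, with 9 false calls among 45037. Rank product made 355 false calls there. Of 3 lists shifted by 1 residual SD, camera recovered 3 with the preset correlation and 0 with an estimated correlation, with 0 false calls among the 36 unshifted lists over 18194 genes. The simulated noise was drawn independently for each probe set, so simulated genes of a list did not vary together. In the data the estimated correlation reached 0.846 for skeletal muscle and 0.803 for adipocyte markers. The 0 false calls therefore do not give the error rate of the preset correlation on these data.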

Results

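GLMT1 cells, a tumour line of the GRS/A mouse strain named after a lung metastasis, were inoculated under the back skin of male mice, and the tumours that grew were profiled on 1-colour Affymetrix arrays. The hosts were GRS/A mice with intact tenascin-C (WT) or GRS/A mice deficient in it (TNKO). Tenascin-C is a glycoprotein of the extracellular matrix. There were 3 tumours per host genotype, described in the labels as biological replicates with 3 mice per group. Hosts were 8 weeks old when taken into the experiment and 10 weeks old in the sample labels. The comparison addresses how the loss of tenascin-C from the host altered gene expression in the tumour. The array medians were 6.57 in each of the 6 arrays. The deposited values differed very little between arrays: the median probe set spanned 5.46e-06 log2 units over the 6 arrays, and 249 of 45037 (0.553%) spanned more than 0.01. Differences are therefore given as TNKO minus WT in deposited log2 units and in residual SDs, the SD of a probe set within the groups, and cannot be read as folds. The number of arrays limits the precision.

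Tnc, the gene removed from the host, was measured by 2 probe sets. The brighter stood at 9.02 ± 0.024 in WT hosts and 8.82 ± 0.018 in TNKO hosts (SD, n = 3 each), a difference of -0.20 (SE 0.016) or -9.37 residual SDs. It was lower in 3 of 3 TNKO tumours than in any WT tumour. Its adjusted p of 0.0537 missed the threshold over all probe sets, and it passed when adjusted over the list alone, the 4 tenascins. The dimmer probe set differed by -0.000671 (adjusted p = 0.125). Subtracting array medians (adjusted p = 1.38e-12) or testing only the brighter probe sets (adjusted p = 0.0359) brought the brighter probe set past the threshold. With medians subtracted the difference itself hardly moved (-0.202). That p therefore reflects the spread assumed by that fit and adds no evidence on Tnc. The same fit called probe sets that differed by at least 1 unit, which as deposited had no unadjusted p under 0.05. Over all alternatives the adjusted p of the brighter probe set ran from 1.38e-12 to 0.519. The labels do not describe the tumour cells as lacking Tnc, and the position of either probe set relative to the altered part of the gene was not used here, so these values do not check the host genotype. Of the other tenascins, Tnn differed by -0.000111 (adjusted p = 0.228), Tnxb by 0.00292 (adjusted p = 0.57) and Tnr by -2.27e-07 (adjusted p = 0.742). As a list the tenascins had an adjusted p of 0.0777 by camera.

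**Figure D1:**
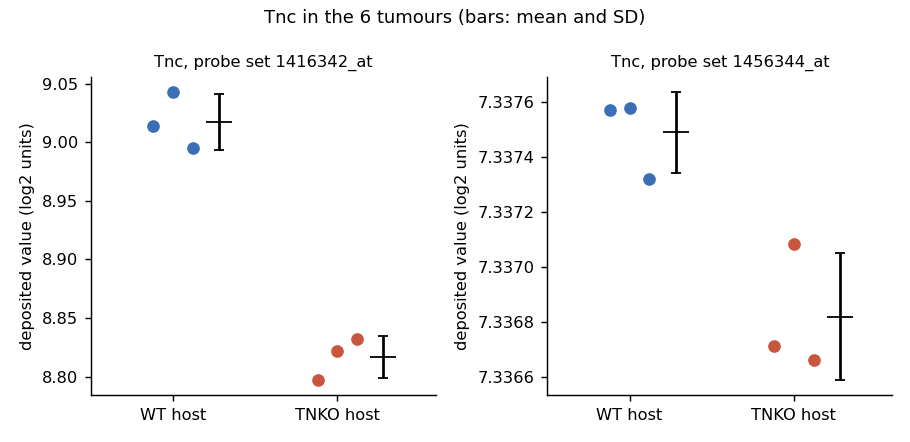
Deposited value in log2 units of both Tnc probe sets in each tumour, by host genotype. Points are tumours and the bars show mean and SD (n = 3); for the brighter probe set, on the left, the means are 9.02 in WT and 8.82 in TNKO hosts, and the 2 vertical axes have different ranges that do not start at 0.

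Of 18194 genes, each read from its brightest probe set, 8 rose and 14 fell in tumours of TNKO hosts. The genes that rose included Atp5g1 and Atp5j2, subunits of mitochondrial ATP synthase, Mrpl20 of the mitochondrial ribosome, and Tomm7 of the outer mitochondrial membrane translocase. Add3, an adducin of the membrane skeleton, the C-type lectin gene Clec2e, Zdbf2 and Utp14b made up the rest. Their rises ran from 6.91e-06 for Tomm7 (SE 5.14e-07, adjusted p = 0.0495) to 4.1e-05 for Utp14b (SE 2.37e-06, adjusted p = 0.0444). In residual SDs the highest was Zdbf2, at 19.6. Hybridisation control probe sets, which hold no mouse RNA, were higher in TNKO hosts in 18 of 18, some by similar amounts. Those for bioC-3 and bioD-3 of the r2 series differed by 4.06e-05 (7.28 residual SDs) and 7.7e-06. None of the 18 passed adjustment, but a hybridisation difference behind the 8 rises cannot be told apart from a host effect. The other probe set of Atp5g1 went the other way, and of the 3 others of Tomm7, 2 went the same way. Of the genes that fell, F3, which encodes tissue factor, the starter of coagulation, had the greatest difference in its brightest probe set, -0.0015 (SE 9.63e-05, adjusted p = 0.0465). Dimmer called probe sets of Gdi2 (-0.00201, adjusted p = 0.0444) and Rab18 (-0.00198, adjusted p = 0.0161) differed by more, so this order depends on the probe set chosen. Socs2, a suppressor of cytokine signalling, fell by 9.77e-05 (adjusted p = 0.0495), and 5 of its 5 other probe sets were lower. Rad52, a DNA repair gene, fell by 0.000113, the Golgi complex gene Cog7 by 0.000122 and the small GTPase Rab18, in its brightest probe set, by 3.34e-05. Slc25a12, a mitochondrial aspartate and glutamate carrier, fell by 3.33e-05, and Fbxl12, Nxpe4, Rsl1d1 and Fam241a fell by 1.64e-05 to 6e-05. Of the 5' probe sets of mouse control genes 4 of 5 were lower and 1 higher, none past adjustment. Those of beta-actin (-0.000402) and Gapdh (-6.99e-05) differed by similar amounts, so a technical difference behind the falls cannot be told apart either. The 10 named falls lost the call under both scalings. Leaving out 1 array took the call from 17 or 18 of the 18 named genes that passed. Wfdc17 and Igha, an immunoglobulin heavy chain constant region, had differences of 0.0142 (adjusted p = 0.1) and 0.01 (adjusted p = 0.0715) and did not pass.

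Over all probe sets, limma called 79 of 45037, 19 higher and 60 lower in TNKO hosts, with absolute differences of 3.68e-06 to 0.00201. None of them differed by at least 1 unit on the deposited scale. A difference of that size was seen in 9 probe sets as deposited, 0 of them at an unadjusted p under 0.05. With array medians subtracted, 9 probe sets with such a difference were called. Probe sets that ranged widest included hair genes high in TNKO tumour 3 alone, such as Krtap8-1 (12.60, against 5.95 to 6.15 in the other tumours). Myh1, low in TNKO tumours 1 and 2, was also among them. At an unadjusted p under 0.05 there were 9144 probe sets (20.3%), 4293 higher and 4851 lower. The 3 TNKO values all lay on one side of the 3 WT values in 12596 probe sets (28%), against 10% by chance. With array medians subtracted, 58 probe sets were called higher and 10 lower, none of them among the 79, and with quantile normalization 0 were called, with 591 at an unadjusted p under 0.05. Both scalings turned the 8 rises into lower values, as they moved the median difference of all probe sets to -0.000764 (medians subtracted) and -0.000538 (quantile normalization), further down than any of the 8 had risen. Rank product called 1453, and made 355 false calls on simulated data. Without WT tumour 1 or 3 the limma count was 0, with 7144 and 6807 at an unadjusted p under 0.05, without TNKO tumour 1 it was 1, without TNKO tumour 2 it was 4 and without TNKO tumour 3 it was 6. Without WT tumour 2 it was 73, 13 higher and 60 lower, of which 14 were among the 79.

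By camera, 7 groups of genes were lower as a set in TNKO hosts. Of 28 hypoxia and glycolysis genes 26 were lower (adjusted p = 4.76e-05, and adjusted p = 0.27 with an estimated correlation). Hk1, a hexokinase, differed by -5.6e-05 (-3.35 residual SDs), Slc2a1, a glucose transporter, by -0.00166 (-2.71 residual SDs) and Ero1a by -0.000782 (-2.65 residual SDs). WT tumour 3 was the highest array in 23 of the 28 genes and TNKO tumour 2 the lowest in 21, and the list passed with each array left out in turn. MHC class I genes were lower in 8 of 8, with an adjusted p of 0.0004 and an adjusted p of 0.188 with an estimated correlation. Among them 5 were lower when adjusted over the list alone: B2m, the light chain of class I molecules, H2-D1, H2-K1 and the peptide transporters Tap1 and Tap2. B2m differed by -3.48e-06, or -3.83 residual SDs. WT tumour 1 was the highest array in 8 of these 8 genes and TNKO tumour 2 the lowest in 5, and this list too passed with each array left out. Interferon-stimulated genes were lower in 21 of 28 (adjusted p = 0.0014, and adjusted p = 0.27 with an estimated correlation), 10 of them at an unadjusted p under 0.05. Stat2, a transcription factor of interferon signalling, differed by -4.89e-05, the chemokine gene Cxcl10 by -0.00145 and Psmb8, an immunoproteasome subunit gene, by -4.13e-05. Without WT tumour 3 the interferon-stimulated genes did not pass (adjusted p = 0.116).

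Lipid and cholesterol synthesis genes were lower in 13 of 18 (adjusted p = 0.000669, and adjusted p = 0.188 with an estimated correlation), while with array medians subtracted the test of this list turned to the higher direction (adjusted p = 0.32). Of these 7 were lower when adjusted over the list alone, among them Fdps (-0.000205), Cyp51 (-2.96e-05) and Sqle (-0.000471), enzymes of the cholesterol pathway. The list passed with each array left out. The mean difference of this list was above 0 while its median and its test were below. Immediate-early and stress genes were lower in 19 of 25 (adjusted p = 0.00193, and adjusted p = 0.279 with an estimated correlation). Dusp1, a MAP kinase phosphatase, differed by -0.000345 and was lower when adjusted over the list alone, and Atf3 and Ier3 differed by -0.000424 and -0.00747. WT tumour 3 was the highest array in 20 of these 25 genes, and without it the immediate-early and stress genes did not pass (adjusted p = 0.334). TGF-beta signalling genes were lower in 16 of 24 (adjusted p = 0.0274, and adjusted p = 0.27 with an estimated correlation). Inhba, an activin subunit gene, differed by -0.0036 and Ccn2 by -0.000183, while Bmp7 differed by 7.11e-05. The TGF-beta signalling genes did not pass without TNKO tumour 1 (adjusted p = 0.166) or without TNKO tumour 3 (adjusted p = 0.0522). In none of these 6 lists did the brightest probe set of a gene pass over all probe sets. A dimmer probe set of Hmgcs1, a gene of cholesterol synthesis, fell (-0.000125, adjusted p = 0.0495), while its brightest differed by -8.46e-06 (adjusted p = 0.592). Probe sets for the 5' ends of mouse control genes moved with these groups, 4 of 5 being lower in all 3 TNKO tumours at an unadjusted p under 0.05, against 2 of 5 at the 3' ends. Of the middle probe sets, 4 of 6 were lower and 1 was higher at that threshold. In the group means 4 of 5 were lower at either end, so a loss particular to the 5' ends was not shown.

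By the same test 5 groups were higher as a set. Oxidative phosphorylation genes were higher in 23 of 29 (adjusted p = 0.00143, and adjusted p = 0.188 with an estimated correlation). Ndufa4 (0.000241) and Ndufb8 (1.37e-05), both of the respiratory chain, were higher when adjusted over the list alone, and Atp5a1 differed by 1.97e-05. TNKO tumour 1 was the highest array in 23 of these 29 genes, and TNKO tumours 2 and 3 in 1 each, and the list passed with each array left out. Neutrophil markers were higher in 12 of 13 (adjusted p = 0.00226, and adjusted p = 0.208 with an estimated correlation). Mmp8, the neutrophil collagenase, differed by 1.81e-05 and was higher when adjusted over the list alone, Elane differed by 3.47e-06 and Csf3r by 3.46e-05. TNKO tumour 1 was the highest array in 7 of the 13 neutrophil genes, and the list passed with each array left out. Endothelial markers were higher in 20 of 22 (adjusted p = 0.0274, and adjusted p = 0.451 with an estimated correlation), with Cldn5, a tight junction gene, at 0.000593, Ptprb at 0.000221 and Mmrn2 at -0.000184. Among endothelial markers TNKO tumour 1 was the highest array in 17 of 22 and WT tumour 3 the lowest in 19, and the list did not pass without WT tumour 3 (adjusted p = 0.302), TNKO tumour 1 (adjusted p = 0.166) or TNKO tumour 2 (adjusted p = 0.0609). Milk protein genes were higher in 9 of 10 (adjusted p = 0.0274, and adjusted p = 0.27 with an estimated correlation). Lao1 differed by 2.55e-06 and the casein gene Csn2 by 1.81e-06. The milk protein genes were dim: 9 of the 10 lay below the median level of all genes (7.09), with a median level of 6.27. Dimness was not limited to this list: 8 of 13 neutrophil, 22 of 26 skeletal muscle and 12 of 18 adipocyte genes also lay below 7.09. Of the endothelial genes 11 of 22 did, and of the oxidative phosphorylation genes 0 of 29. The milk protein genes did not pass without WT tumour 1 (adjusted p = 0.0866), TNKO tumour 2 (adjusted p = 0.0807) or TNKO tumour 3 (adjusted p = 0.0564). Hybridisation control probe sets, which hold no mouse RNA, moved with these groups: 16 of 18 were higher in all 3 TNKO tumours than in any WT tumour, and 13 had an unadjusted p under 0.05. Quantile normalization and subtraction of array medians, which move the median difference of all probe sets down (-0.000538 and -0.000764), left 14 and 18 of the 18 lower in TNKO hosts. With that common shift oxidative phosphorylation genes were lower in 28 and 29 of 29, endothelial markers in 21 and 22 of 22, neutrophil markers in 10 and 11 of 13, and milk protein genes in 9 and 10 of 10. Tested against the other genes, the neutrophil markers stayed a higher group under both scalings, and the other 3 lists did not pass. Only 3 and 2 of the 13 neutrophil genes were higher there. As deposited the mean difference of the neutrophil list (0.000781) lay far above its median (5.22e-06), so few of its genes carried that mean.

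Skeletal muscle markers were the remaining lower group, in 26 of 26 genes (adjusted p = 0.000377, and adjusted p = 0.573 with an estimated correlation), and adipocyte markers the remaining higher group, in 18 of 18 (adjusted p = 0.00104, and adjusted p = 0.554 with an estimated correlation). Taken singly, 0 of the 26 muscle genes and 1 of the 18 adipocyte genes had an unadjusted p under 0.05 by limma. Both lists followed tumours 1 and 2 of the TNKO hosts, and both passed with each array left out. Those fits kept the preset correlation of 0.01, against estimates of 0.846 and 0.803, and at least 1 of these 2 tumours. Passing there therefore adds no support. Acta1, skeletal muscle actin, stood at 7.54 and 7.58 in tumours 1 and 2 and at 8.31 in TNKO tumour 3, against 8.18 to 8.37 in WT tumours. Myh2 and Myh7, myosin heavy chains, differed by -0.24 and -0.000571. Tumours 1 and 2 were the 2 lowest arrays in 25 of the 26 muscle genes, and the 2 highest in 17 of the 18 adipocyte genes. Fabp4, a fatty acid carrier, stood at 9.62 and 9.46 in them, at 9.06 in TNKO tumour 3 and at 8.54 to 9.16 in WT tumours. Lpl differed by 0.31 and Acvr1c by 4.62e-06. The endothelial markers shared this order of arrays: TNKO tumour 1 was the highest and WT tumour 3 the lowest in most genes of both lists (17 and 13 of 18 adipocyte genes, 17 and 19 of 22 endothelial genes). On a scale from TNKO tumours 1 and 2 at 0 to the WT mean at 1, TNKO tumour 3 lay at a median of 0.956 in the adipocyte and 0.873 in the endothelial list. Oxidative phosphorylation genes shared part of this order. TNKO tumour 1 was the highest array in 23 of 29 of them and WT tumour 3 the lowest in 9, with TNKO tumour 3 at a median of 0.779. Adipocyte markers stayed higher in 15 of 18 after quantile normalization and after subtraction of medians, against the common downward shift.

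**Figure D2:**
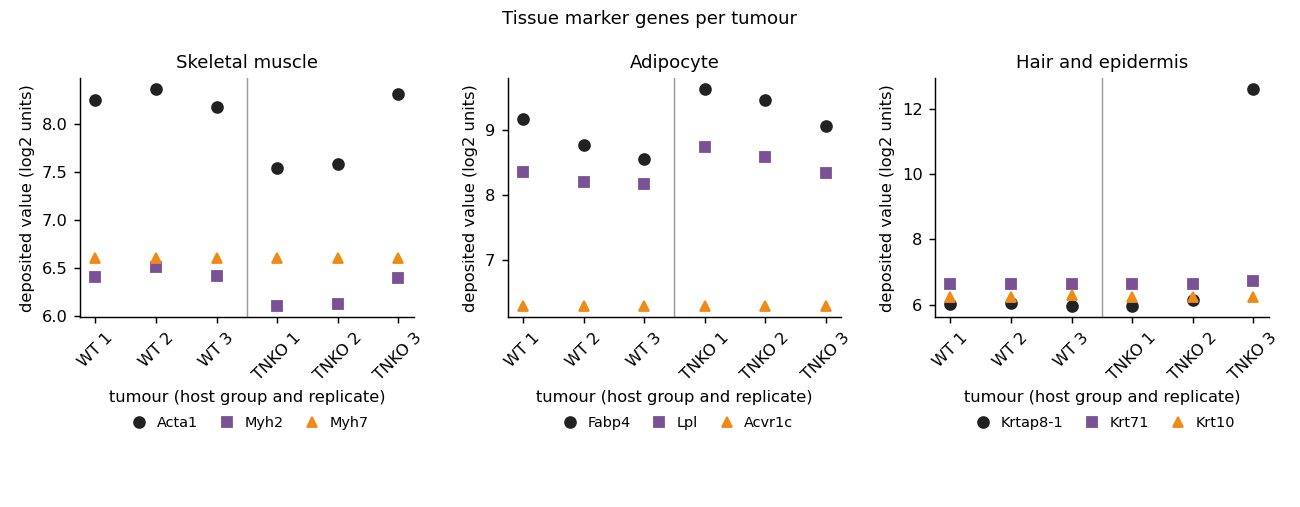
Deposited value in log2 units of 3 genes per tissue in each of the 6 tumours, 1 point per array, with a vertical line between host genotypes. Acta1 is at 7.54 and 7.58 in TNKO tumours 1 and 2 and at 8.18 to 8.37 in the others, and Krtap8-1 is at 12.60 in TNKO tumour 3; the vertical axes differ and do not start at 0.

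The other 27 lists did not pass with camera's preset correlation. Among matrix groups, fibrillar and network collagens were higher in 15 of 19 genes (adjusted p = 0.464), other matrix glycoproteins and proteoglycans in 21 of 32 (0.744) and fibroblast markers in 18 of 22 (0.265). Matrix-degrading enzymes and inhibitors had an adjusted p of 0.552, tenascin-C receptors and ligands 0.501, smooth muscle, myofibroblast and pericyte markers 0.501, angiogenic factors 0.29, lymphatic endothelial markers 0.29 and epithelial-mesenchymal transition genes 0.29. Among immune cells, macrophage and monocyte markers had an adjusted p of 0.588, dendritic cell and antigen presentation markers 0.0777, mast cell and basophil markers 0.211, T cell and NK cell markers 0.552, and B cell and plasma cell markers 0.29. Cytokines and chemokines stood at 0.464. Cell cycle genes were higher in 25 of 31, with an adjusted p of 0.0727, and passed without TNKO tumour 3 (adjusted p = 1.63e-05), as dendritic cell markers did in the lower direction (adjusted p = 0.0131). Other lists that passed with 1 array left out were fibroblast markers without WT tumour 1 (higher, 0.0299), cell cycle genes without WT tumour 2 (higher, 0.0152), and, without WT tumour 3, dendritic cell markers (lower, 0.0369), mast cell and basophil markers (lower, 0.0289) and skin keratinocyte and hair markers (higher, 0.02). Epithelial and mammary tumour markers had an adjusted p of 0.872, skin keratinocyte and hair markers 0.588, nerve and Schwann cell markers 0.368 and erythrocyte markers 0.438. Apoptosis regulators had 0.438, Wnt signalling genes 0.963, Notch signalling genes 0.862, cytosolic ribosomal protein genes 0.274, Y-linked genes 0.464, and genes flanking Tnc on chromosome 4 0.394. Median, mean and test differed in sign for the matrix-degrading, angiogenic, epithelial-mesenchymal, Wnt, Notch and apoptosis lists. Of the Y-linked genes Eif2s3y differed by 4.56e-05, Kdm5d by 1.05e-05 and Uty by 3.65e-06, and Xist, tested as a single gene, by 1.31e-06 (adjusted p = 0.145).

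The 12 list calls were made with the preset correlation only. With an estimated correlation 0 of 39 lists passed adjustment and 6 had an unadjusted p under 0.05. That version recovered 0 of 3 shifted lists in the simulation, so losing the call under it says little about a list. The estimate lay below the preset for MHC class I (-0.0205), lipid and cholesterol synthesis (-0.0469) and oxidative phosphorylation genes (-0.0329). So it did for neutrophil (-0.0243), TGF-beta (-0.0206) and milk protein genes (-0.107). Correlation among their genes therefore does not account for those lost calls. Fry's directional test called 2, the tenascins (adjusted p = 0.0276) and the genes flanking Tnc (adjusted p = 0.005). With array medians subtracted 8 lists passed, 3 of them among the 12, and with quantile normalization 13 passed, 7 of them among the 12. Regrouping the 6 arrays against host genotype called up to 17 lists, more than the 12 called here.

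**Figure D3:**
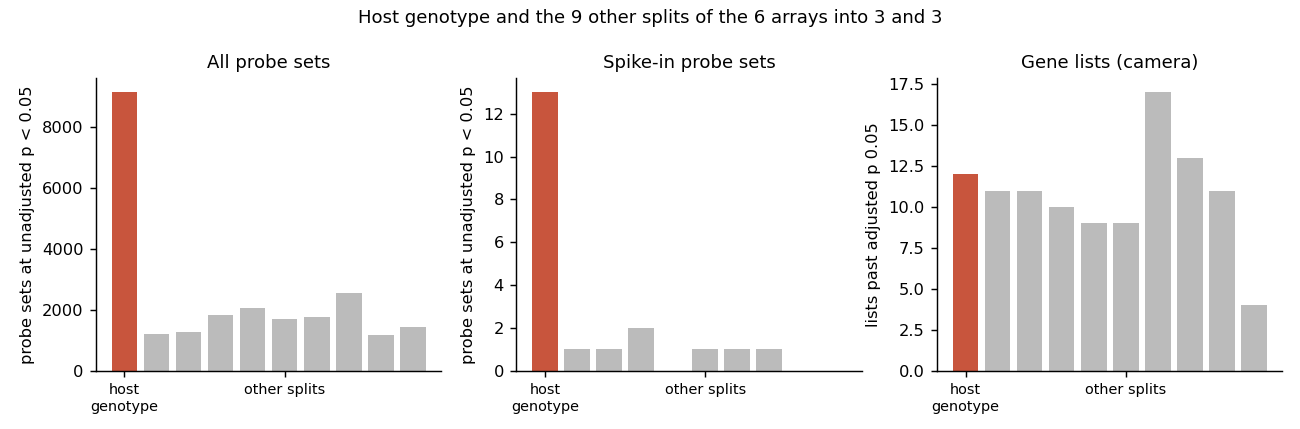
Number of probe sets and of spike-in probe sets at an unadjusted p under 0.05, and of gene lists past an adjusted p of 0.05, when the 6 arrays are divided by host genotype (left bar of each panel) and in the 9 other ways into 3 and 3. Host genotype gives 9144 probe sets and 13 spike-ins, against at most 2555 and 2 otherwise, and 12 lists against at most 17.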

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

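The counts of other splits for probe sets, the position of TNKO tumour 3 and the breakdown of the control probe sets were tests chosen only after the result was seen. The spike-in control probe sets, which stand outside the comparison of genes, gave a signal: 13 of 45 had an unadjusted p under 0.05. All 13 were among the 18 hybridisation controls and higher in TNKO hosts, and none passed adjustment; under quantile normalization 14 of the 18, and with subtracted medians 18 of the 18, were lower in TNKO hosts, as these scalings moved the median difference of all probe sets down (-0.000538 and -0.000764). The 27 labelling controls gave 0 at an unadjusted p under 0.05, and whether they were detected was not tested.

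About 1 in 5 probe sets, 9144 or 20.3%, had an unadjusted p under 0.05 for host genotype. A hybridisation difference that moves with host genotype is a candidate explanation, since the spike-in share was 28.9%, at least as high as that of the mouse probe sets. Its exact 95% interval (16.4 to 44.3) treats probe sets as independent, though several read the same spike-in, so it cannot decide this comparison. The share was made up of 13 of 18 hybridisation controls and 0 of 27 labelling controls. The labelling controls reached at most 6.47, below the median tested probe set at 6.57. Muscle or fat taken with the tumours could also contribute: over 202 genes of the other called lists, TNKO tumour 3 lay at a median of 0.351 (95% bootstrap interval 0.258 to 0.535) between TNKO tumours 1 and 2 at 0 and the WT mean at 1, with lists that went apart (endothelial 0.873, oxidative phosphorylation 0.779, neutrophil 0.168, immediate-early 0.138), which leaves this open. The bootstrap interval resamples genes, though they were read from 1 tumour and genes of a list can vary together. The lists were also called in a comparison that holds TNKO tumour 3, which can favour positions near tumours 1 and 2. The 10 splits of 3 against 3 are too few for a share under 0.05, and the highest other split gave 2555 probe sets. An effect of host genotype on the tumours stays open and cannot be told apart from a technical difference between the groups.

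For the called probe sets the real split gave 79 and the highest other 0, and 1 split, the real one, gave at least as many. Calls with a difference of at least 1 unit numbered 0 in 10 of 10 splits, so nothing can be compared. For the gene lists the real split gave 12 and the highest other 17, with 3 splits at or above the real one. With 10 splits no share can lie under 0.05.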

How the results depend on the processing

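The filter on range, the fit without moderation and camera on ranks were alternatives chosen only after the data were seen. The 79 called probe sets became 0 with quantile normalization, 0 with the replicate block (7816 at an unadjusted p under 0.05), 0 among probe sets spanning at least 0.001, 2 without moderation, 285 among probe sets above the median level and 1453 by rank product, which made many false calls on simulated data. Leaving out 1 array gave 0 to 73. Subtracted medians gave 68, of which 9 had a difference of at least 1 unit, where there were 0 such calls as deposited. As deposited, 9 probe sets differed by that much, 0 of them at an unadjusted p under 0.05. The 9144 at an unadjusted p under 0.05 became 591 with quantile normalization, 87 with subtracted medians, 5420 above the median level and 155 with the filter on range. The filters test fewer probe sets, and the leave-one-out and block fits have fewer residual degrees of freedom. The Tnc difference passed with subtracted medians (-0.202) and above the median level (-0.20), and missed the threshold elsewhere, with adjusted p from 0.0517 to 0.519. The 12 lists became 3 with the filter on range, 0 with an estimated correlation and 2 with fry, neither of them among the 12, and 8 to 14 under the others. Of the 8 with subtracted medians only 3 were among the 12, the neutrophil, muscle and adipocyte lists, so that 6 lost the call and 3 turned, and of the 13 with quantile normalization 7 were, so that 4 lost the call and 1 turned.

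Quantile normalization and subtracted medians turned the 8 rises: Utp14b to -0.000565 and -0.000723, Clec2e to -0.000606 and -0.00074, Add3 to -0.000763 and -0.000752, Atp5g1 to -9.49e-05 and -0.000753, Zdbf2 to -0.000384 and -0.000755, Atp5j2 to -0.000967 and -0.000756, Mrpl20 to -0.000694 and -0.000756, Tomm7 to -0.00171 and -0.000757. The direction of oxidative phosphorylation genes turned under both (adjusted p = 0.483 and 0.985), and under subtracted medians so did those of milk protein genes (0.985) and lipid and cholesterol synthesis genes (0.32). These scalings moved the median probe-set difference to -0.000538 and -0.000764, from 9.97e-08 as deposited, because the array median of TNKO tumour 3 stood 0.00231 above the others while its median probe-set difference was -5.62e-08. Of 115 named genes that did not pass, 58 changed sign under each scaling, as did 12 and 8 of the 27 lists that did not pass. The other alternatives turned no called gene or list. Same-numbered tumours had correlations of 0.175, -0.218 and -0.112 of their deviations from the group means, so the replicate block, under which all 18 called named genes lost the call and the lists numbered 14, rests on numbers alone, and not every sample correlated best with its own number.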

Other observations

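All tests in this part were chosen only after the result was seen. In TNKO tumour 3, genes of the hair shaft stood apart: 36 of 38 keratin-associated protein genes were highest there, 13 of them by at least 1 log2 unit, with Krtap8-1 at 12.60 against 5.95 to 6.15 in the other tumours. After quantile normalization or subtraction of medians it was 28 of 38.

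Skeletal muscle markers were low in TNKO tumours 1 and 2. TNKO tumour 3 lay at a median of 1.26 (quartiles 1.15 and 1.36) on the scale from TNKO tumours 1 and 2 at 0 to the WT mean at 1, but this restates the pattern and rests on a single tumour, so a host effect alike in all 3 TNKO tumours stays open. Different amounts of muscle in the excised samples stay open as well: tumours 1 and 2 were the 2 lowest arrays in 96.2% of the 26 genes, but this too restates the pattern, in genes that vary together, and any other influence shared by these genes would give it too. Myh1, the highest of them in WT tumours, stood at 6.17 and 6.64 there, against 8.65 to 9.44 in WT tumours and 9.28 in TNKO tumour 3, and adipocyte markers showed the opposite order, with TNKO tumour 3 at a median of 0.956. A host effect that differs between TNKO tumours was not tested.

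For the hair genes, an upward shift of the whole array is argued against by the probe sets as a whole. That array was highest in 15.5% of all probe sets, and its median probe-set difference from the mean of the others was -5.62e-08. It was highest in 94.7% of keratin-associated protein genes (exact 95% interval 82.3 to 99.4), but this share restates the pattern. The interval treats the genes as independent, though they were read from 1 tumour. The interfollicular epidermis genes, which whole skin taken with the tumour would also bring, did not follow: TNKO tumour 3 was highest in 1 of 10. When WT tumour 3, itself the highest in 7, is set aside, it was highest in 3 of 10. TNKO tumour 3 exceeded the mean of the other arrays by at most 0.000461 in these genes, against 6.57 for Krtap8-1. The count rests on 1 tumour and on mostly dim probe sets, and sizes cannot be compared between probe sets on this scale. It therefore cannot decide whether whole skin was taken. Whole skin, hair follicle and hair shaft material in that sample stay open as possible sources, and a biological explanation was not tested.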
